A study of Mus musculus with 24 samples.

How the data were processed

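RNA of 24 organoid samples was measured, 4 control and 4 irradiated samples at each of 24, 48 and 96 h. Per the labels' protocols, RNA was extracted with the Isolate II RNA Mini kit (Bioline), and biotin-labelled cDNA was made with the Nugen Ovation Pico SL kit and Encore BiotinIL module. The authors deposited a table of Illumina BeadChip signals, which per the file headers are mean bead signals per probe, as intensity values on a linear scale. From the values, these were neither normalized between arrays nor background subtracted. Per the file headers the same table holds a detection p-value for each probe and array, which falls in steps of 0.00125, as 798 negative control beads would give. The authors also deposited a table of processed intensity values. Its columns hold the same values up to ties, in the order of the first table, so it was taken to be quantile normalized on the linear scale with no background subtraction. The software used by the authors is not given in the sources used here.

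The signals were corrected for background with normexp fitted from the detection p-values, with an offset of 16, quantile normalized over the 24 arrays and put on the log2 scale (neqc of limma 3.58.1, in R 4.3.3, with version 1.17.8 of data.table). Probes detected at a p under 0.05 on at least 4 arrays were kept, 15056 of 25697, and the brightest probe stood for each symbol, which left 10798 genes. Arrays of a group correlated at 0.954 to 0.994 over these genes. Among 2878 genes with several detected probes, probes were called in opposite directions for 10 at 24 h, 1 at 48 h and 0 at 96 h. Of the named genes with several detected probes, another probe differed in call from the brightest for 7 of 24 at 24 h, 5 of 23 at 48 h and 7 of 21 at 96 h, over all probes. Names are those of the array. Of 18138 symbols, 14307 equal a current symbol of the mouse annotation of assembly GRCm38.p6, 2927 older ones matched 1 current symbol and 904 had no match. No coordinates are given.

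A linear model with 1 mean per group was fitted to all 24 arrays with limma, with moderated variances (18 residual and 4.10 prior degrees of freedom, prior SD 0.211). Irradiated and control samples were contrasted at each time, and these effects were contrasted between times. P-values were adjusted per contrast over all genes tested (Benjamini-Hochberg), two-sided, and genes with an adjusted p under 0.05 were called. Where a gene was not detected on any array of a group, only a bound on its fold is given. It sets the brighter group's mean against the dim group's mean of, per array, the lowest signal among detected probes or the probe's own, whichever was higher. The number of detected probes per array was compared with an exact two-sided permutation test over 70 splits, adjusted over the 3 times.

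The 32 gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. They cover p53 targets, mitosis, DNA replication, DNA repair, apoptosis, crypt base and position +4 stem cells, Wnt targets, the Notch pathway, fetal-like epithelium, YAP targets, enterocytes, HNF4A targets and intestinal transcription factors. They also cover Paneth, goblet, enteroendocrine and tuft cells, the interferon response, inflammation, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, ribosome biogenesis, the unfolded protein response, NRF2, hypoxia, xenobiotic metabolism, mesenchyme, immune cells, endothelium and erythroid cells. Lists were written from general knowledge and share genes.

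The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per time, the 10 largest rises and 10 largest falls among called genes whose irradiated and control values do not overlap, leaving out clone names. It adds a fixed set of 14 genes and, per list, the 3 called members with the largest change, and for differences between times the 5 largest called in each direction. The text names part of these, and some genes that the rule picks are not reported here. Differences between times are also given for genes that the rule names at single times. Of the fixed set, Mki67, Alpi, Muc2 and Clu had no probe in the table, and the probe of Dclk1 was not detected on enough arrays.

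The comparison of controls between times was added after seeing the data, as were its other scalings and the leaving out of control arrays. Alternatives tried were no background correction, an offset of 50, median scaling, cyclic loess, quantile normalization within a chip, the authors' deposited processed values, other detection filters, fits to the arrays of the times compared, a trended robust variance model, array weights, the mean of the probes of a gene, other thresholds, a replicate block and leaving out each array. Added after seeing the data were the number of detected probes or the mean of 49 histone genes as a covariate, leaving out the 5 arrays with under 12000 detected probes, and leaving out each array in the tests of gene lists. The scripts were tested on simulated data with 10798 genes and 100 genes changed by each size. At 24 h, 30 genes changed by 0.5 log2 units and 84 changed by 1 were called, with 3.39% false calls. The numbers were 22, 90 and 8.20% at 48 h, 28, 85 and 7.38% at 96 h, and 9, 54 and 5.97% for the difference between 96 and 24 h. A shift of -0.5 in the mitosis list at 24 h was called, as was 1 of 31 other lists. The simulated noise was independent between genes, so these shares need not hold for real arrays, where genes vary together.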

Results

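Small intestinal organoids from C57BL/6 mice are epithelial cultures that hold crypt stem cells together with Paneth, goblet, enteroendocrine and absorptive cells. They were grown with EGF (50 ng/ml), Noggin and R-spondin. Part of the cultures received 6 Gy of gamma radiation 3 days after reseeding, and RNA was taken 24, 48 and 96 h later from irradiated organoids and from organoids that were not irradiated. Each of the 6 groups had 4 samples, 24 in all, and each time point had its own controls. The comparisons ask how gene expression in the epithelium differs between irradiated and control organoids at each time, and how that difference itself changes with time.

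Transcripts were measured on Illumina mouse BeadChips, on which the brightness of a probe reports the abundance of its transcript. The 8 arrays of a time point shared 1 chip, so each irradiation effect is a comparison within a chip. Controls held the first 4 positions of every chip and irradiated samples the last 4, so position on the chip cannot be told apart from irradiation. The labels do not say whether the samples of a group came from separate cultures, and p-values measure the spread between these samples, which may be technical. Of 25697 probes, 13012 ± 485 (SD, n = 4) were detected in the 24 h controls and 11469 ± 1475 in the 24 h irradiated samples. The corresponding numbers were 14071 ± 49.3 and 13660 ± 783 at 48 h, and 12992 ± 895 and 12118 ± 1251 at 96 h. The 3 differences did not pass an exact two-sided permutation test (p = 0.114, 0.457 and 0.229; adjusted p = 0.343, 0.457 and 0.343). Single arrays ranged from 9738 probes, in irradiated 24 h replicate 3, to 14751, in irradiated 48 h replicate 1. The number of arrays limits the precision, with a median standard error of 0.17 log2 units for an irradiation effect.

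At 24 h after irradiation, transcripts of p53 target genes and of absorptive enterocytes were higher. Transcripts of dividing cells were lower, as were some of those of crypt base stem cells. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 8.93 ± 0.13 to 10.07 ± 0.04 log2 units (mean ± SD, n = 4 arrays each; log2 fold change 1.14, SE 0.12, limma adjusted p = 2.13e-07). Lgr5, the R-spondin receptor that marks crypt base stem cells, fell by 1.47 on the log2 scale (SE 0.13, adjusted p = 1.87e-08), a 2.77-fold change. Ly6a, a surface antigen found on regenerating and fetal-like intestinal epithelium, rose 4.31-fold (log2 fold change 2.11, SE 0.12, adjusted p = 7.1e-11). All 28 tested enterocyte genes rose.

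Among 28 tested p53 targets, 24 rose and none fell, the same numbers when adjusted over the list alone, and the median log2 fold change was 0.95 (camera adjusted p = 1.26e-18). Plk2, a kinase gene, rose 4.71-fold, and Phlda3, whose product restrains Akt signalling, rose 3.46-fold. Ddit4l was not above background in the controls and was at least 2.79-fold higher. Mdm2, the ubiquitin ligase that degrades p53, rose by 0.89 and Ccng1, cyclin G1, rose 2.20-fold. The apoptosis list shares 5 genes with the p53 list. Of its 27 tested genes 7 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0243). Bbc3, which encodes the pro-apoptotic protein PUMA, rose by 1.14, the death receptor gene Fas by 0.96 and the BCL2 family gene Bok by 0.78. Of the 2 other probes of Fas 1 rose, by 0.68, and 1 did not pass (0.36, adjusted p = 0.334 over all probes).

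Of 21 mitosis genes, 19 fell (21 adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 1.86e-11). Nusap1, a spindle protein gene, fell by 0.95. Of 29 DNA replication genes, 11 fell (13 adjusted over the list alone, median -0.29, camera adjusted p = 0.000126), among them the thymidine kinase gene Tk1, by 0.98, and the clamp loader subunit gene Rfc3, by 0.59. Of 23 DNA repair genes, 7 fell (10 fell and 1 rose adjusted over the list alone, median -0.29, camera adjusted p = 0.00276), but this call was lost with an estimated correlation (adjusted p = 0.0705). H2afx, which encodes the histone variant H2AX, fell by 0.72, and the brightest probe of the helicase gene Blm fell by 0.65. Of its 3 other probes 1 fell, by 1.10, and 2 did not pass (-0.42 and -0.47, adjusted p = 0.265 and 0.268 over all probes). Of 19 genes of ribosome biogenesis and MYC, 5 fell (median -0.25, camera adjusted p = 0.00637), among them Nol5, by 0.50, and nucleolin (Ncl), by 0.38.

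The crypt base list was called lower, with 8 of 19 genes lower and 2 higher (the same numbers adjusted over the list alone, median -0.25, camera adjusted p = 0.00313). That call was lost with median scaling (camera adjusted p = 0.0637). Olfm4, a secreted stem cell marker, fell by 1.29, while Ascl2, a Wnt-driven transcription factor of the stem cells, rose 3.80-fold and the brightest probe of the adhesion receptor gene Cd44 rose by 0.82. Of the 5 other probes of Cd44, 2 rose, by 0.86 and 0.84, and 3 did not pass (0.54, 0.50 and 0.08, adjusted p = 0.108, 0.0927 and 0.805 over all probes). The Wnt target list shares 10 genes with the crypt base list and did not move one way (3 of 14 rose and 3 fell, camera adjusted p = 0.404). Of 7 position +4 genes, 1 fell (camera adjusted p = 0.248). This was Mex3a, an RNA-binding protein gene, which was not above background after irradiation and was at least 1.27-fold lower. In the Notch list, 3 of 14 genes rose and 2 fell (camera adjusted p = 0.713), with rises of the ligand gene Jag1, by 1.12, and the target gene Hey1, by 0.90.

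Genes of fetal-like and regenerating epithelium rose in 15 of 21 cases and fell in none (17 and none adjusted over the list alone, median 1.02, camera adjusted p = 7.81e-16). The annexin genes Anxa3 and Anxa1 rose 4.27-fold and 3.60-fold. Of 11 YAP targets, 4 rose and 1 fell, and the list did not pass (camera adjusted p = 0.0709), though it did without control 24 h replicate 3 (adjusted p = 0.0498) or irradiated 24 h replicate 3 (adjusted p = 0.0151). Areg, the EGF receptor ligand amphiregulin, rose 4.88-fold; the tissue factor gene F3 and the matricellular gene Ctgf were not above background in controls and were at least 1.97-fold and 1.85-fold higher. Of 14 inflammation genes, 5 rose (median 0.51, camera adjusted p = 0.00031), among them the cytokine gene Il18, by 1.48, and the antimicrobial lectin gene Reg3b, by 1.42. The interferon list did not pass (1 of 10 rose and 0 adjusted over the list alone, camera adjusted p = 0.447).

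The enterocyte rise had a median of 0.71 (28 of 28 adjusted over the list alone, camera adjusted p = 1.64e-20). The glucose transporter gene Slc2a2 rose 2.89-fold, the brush border protease gene Mep1b 2.64-fold and the peptide transporter gene Slc15a1 2.61-fold. HNF4A targets, which share 11 genes with the enterocyte list, rose in 15 of 24 cases and fell in 2 (17 and 2 adjusted over the list alone, median 0.46, camera adjusted p = 1.23e-06). The transthyretin gene Ttr was among the falling members, by 1.62. Hnf4a itself fell by 0.45 (adjusted p = 0.00715). Among 21 intestinal transcription factors, 2 rose, Creb3l3 by 1.08 and Isx by 0.93, and 6 fell, with Elf3 the largest of them at -0.67 (3 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.311). The 2 other probes of Elf3 did not pass (-0.67 and -0.41, adjusted p = 0.209 and 0.0517 over all probes). Of 21 xenobiotic metabolism genes, 18 rose (19 adjusted over the list alone, median 0.67, camera adjusted p = 1.43e-14), including the cytochrome genes Cyp3a25 and Cyp3a11 at 2.72-fold and 2.53-fold. Of 21 genes of fatty acid oxidation and PPAR targets, 7 rose and 1 fell (median 0.19, camera adjusted p = 0.00281; adjusted p = 0.0757 with an estimated correlation). Acaa1b, a peroxisomal thiolase gene, rose by 1.09.

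Of 25 enteroendocrine genes, 13 rose (17 adjusted over the list alone, median 0.68, camera adjusted p = 2.6e-10), among them the hormone genes Cck, 2.54-fold, Gcg, 1.26 on the log2 scale, and Tac1, 2.38-fold. Chga, the granule protein chromogranin A, rose by 0.97 (adjusted p = 0.0309), a call that was lost without control 24 h replicate 3 (0.84, adjusted p = 0.0965), control 24 h replicate 4 (0.87, adjusted p = 0.0862) or irradiated 24 h replicate 2 (0.83, adjusted p = 0.086). Of 15 Paneth cell genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.000403; adjusted p = 0.117 with an estimated correlation). The matrilysin gene Mmp7 rose 2.38-fold, Ang4 1.81-fold and the lysozyme gene Lyz1 1.29-fold. Of 16 goblet cell genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.00804; adjusted p = 0.0533 with an estimated correlation). Clca3, a secreted goblet cell protease gene now named Clca1, rose 3.23-fold, Scin 3.16-fold and the zymogen granule gene Zg16, listed as 1810010M01Rik, 2.32-fold. None of 9 tuft cell genes passed (camera adjusted p = 0.91).

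Hypoxia and glycolysis genes fell in 10 of 18 cases (11 adjusted over the list alone, median -0.34, camera adjusted p = 1.83e-06). Ankrd37, a target of hypoxia-inducible factor, fell by 2.02, Egln3 by 1.07 and Ero1l by 0.97. Of 19 cholesterol synthesis genes, 12 fell (14 fell and 1 rose adjusted over the list alone, median -0.35, camera adjusted p = 5.47e-06), among them lanosterol synthase (Lss), by 0.78. Of 20 NRF2 and glutathione genes, 12 rose (14 adjusted over the list alone, median 0.47, camera adjusted p = 7.42e-08), with the heme oxygenase gene Hmox1 at 4.58-fold and the glutathione synthesis gene Gclc at 2.24-fold. In the unfolded protein and integrated stress response list, 3 of 20 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.342). The probes of the transcription factor gene Ddit3 were called in opposite directions, 1.30 for the brighter one and -0.83 for the other (adjusted p = 0.0419), so its direction is uncertain. Chac1, a glutathione-degrading enzyme, fell by 1.95. None of 25 oxidative phosphorylation genes passed (camera adjusted p = 0.807). Lists of other cell types did not pass either (camera adjusted p = 0.311 for mesenchyme, 0.763 for immune cells, 0.342 for endothelium and 0.73 for erythroid cells), with at most 1 gene higher in each.

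Clone names left out, the 10 largest fitted rises at 24 h included Mbl2, a lectin of innate immunity that was not above background in controls and was at least 5.2-fold higher. V1rh21 (a vomeronasal receptor gene), Cacna1f (a calcium channel subunit), Cxcr5 (a chemokine receptor of B cells), Fmod (a matrix proteoglycan) and Abca8b (a transporter) rose by 2.94, 2.92, 2.86, 2.80 and 2.80 on the log2 scale. Fmnl3, H2-T10, Oprl1 and Duxbl rose by 2.78, 2.74, 2.64 and 2.63. The other probe of Abca8b did not pass (0.68, adjusted p = 0.0931 over all probes), and of the 2 others of Fmnl3 1 rose, by 0.63, and 1 did not pass (0.30, adjusted p = 0.215). Within groups these 10 genes varied together, with a median correlation over pairs of genes of 0.40. Among the largest falls were those in Stc2, a secreted glycoprotein gene (-2.13), Ankrd37, Chac1 and the chloride channel accessory gene Clca4 (-1.84). Others were Lmcd1 (-1.76), the transporter gene Slc16a12 (-1.75), neuritin (Nrn1; -1.68), Tmem117 (-1.64) and Ak3l1, which was not above background after irradiation and at least 1.88-fold lower.

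In all, 1204 genes were higher and 1354 lower at 24 h among 10798 tested, 293 and 94 of them by at least 2-fold. The irradiated and control values did not overlap in 2134 of these genes, and in 3105 of all genes tested against 309 given by chance. With median scaling in place of quantile normalization the split was 464 higher and 4925 lower (8.61% higher against 47.1%), and with cyclic loess 1481 and 680 (68.5%). The lower count was 680 without the 5 arrays that had the fewest detected probes and 789 with the number of detected probes as a covariate. Median scaling ended the calls of the apoptosis, crypt base, goblet and fatty acid oxidation lists (camera adjusted p = 0.521, 0.0637, 0.0637 and 0.249). The YAP list passed with it (0.000842), with that covariate (0.0108) and without those 5 arrays (0.00811), and the endothelial list with median scaling (0.0193).

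**Figure D1:**
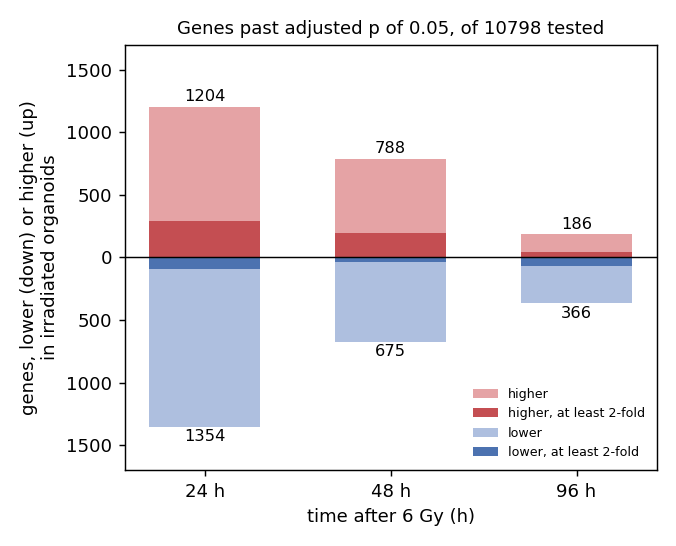
Number of genes higher (above the line) and lower (under the line) in irradiated than in control organoids at 24, 48 and 96 h, of 10798 tested, with changes of at least 2-fold in the darker shade. The counts were 1204 and 1354 at 24 h, 788 and 675 at 48 h, and 186 and 366 at 96 h; with median scaling the share of higher genes was lower at each time (8.61%, 30.0% and 11.3%).

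**Figure D2:**
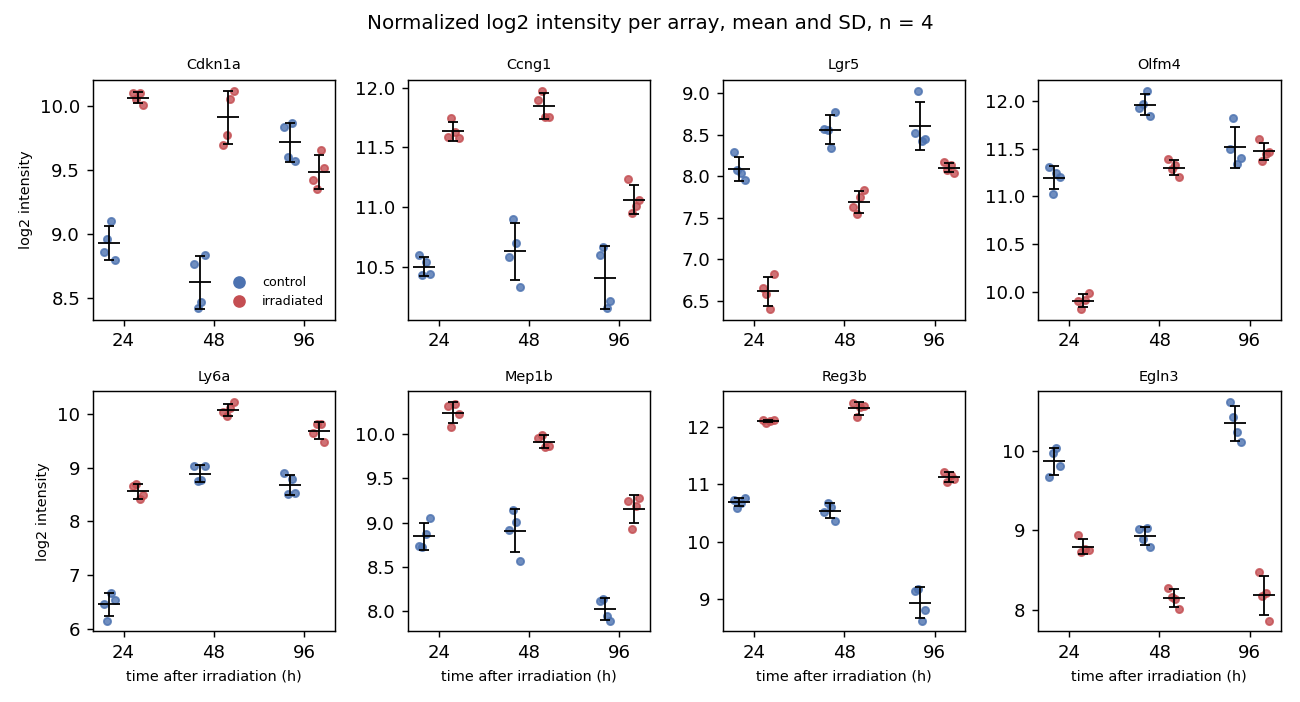
Normalized log2 intensity (vertical axis) of 8 genes at 24, 48 and 96 h (horizontal axis) in control (blue) and irradiated (red) organoids, 1 point per array, with bars at the mean and SD of 4 arrays. Lgr5 and Olfm4 lay lower in all 4 irradiated arrays at 24 and 48 h, and Ly6a, Mep1b and Reg3b lay higher in all 4 at each time.

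At 48 h, p53 targets, fetal-like genes and enterocyte genes were again higher, and genes of dividing cells and of the crypt base were again lower. Cdkn1a rose from 8.62 ± 0.21 to 9.91 ± 0.21 log2 units (mean ± SD, n = 4 arrays each; log2 fold change 1.29, SE 0.12, limma adjusted p = 7.77e-08). Lgr5 fell by 0.87 (SE 0.13, adjusted p = 5.16e-05) and Olfm4 by 0.66 (SE 0.10, adjusted p = 8.45e-05). Anxa8, an annexin gene of the fetal-like list, rose 4.53-fold and the squamous envelope gene Sprr1a rose 4.27-fold. Reg3b rose 3.45-fold (log2 fold change 1.79, SE 0.11, adjusted p = 3.44e-10).

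Of 28 p53 targets, 20 rose (20 adjusted over the list alone, median 0.69, camera adjusted p = 1.21e-20), with the death receptor gene Eda2r at 3.60-fold, Ddit4l at 3.75-fold and Phlda3 at 3.26-fold; Mdm2 rose by 0.69 and Ccng1 by 1.22. In the apoptosis list, 5 of 27 rose and 1 fell, including rises of the effector gene Bax, by 1.02, and Bbc3, by 0.85 (other probes 0.67 and, not called, 0.72). That list did not pass (camera adjusted p = 0.0703), and it did without control 48 h replicate 3 (adjusted p = 0.0331). Of 21 mitosis genes, 7 fell (9 adjusted over the list alone, median -0.31, camera adjusted p = 2.25e-05), among them the checkpoint kinase gene Ttk, by 0.65, and cyclin A2 (Ccna2), by 0.61. DNA replication genes fell in 8 of 29 cases (10 adjusted over the list alone, median -0.30, camera adjusted p = 3.07e-05), with Prim1 at -0.62 and E2f1 at -0.77. DNA repair genes fell in 7 of 23 cases (8 adjusted over the list alone, median -0.32, camera adjusted p = 3.39e-05), with the checkpoint kinase gene Chek1 at -0.70 and Brca2 at -0.78. The other probe of Brca2 did not pass (-0.32, adjusted p = 0.413 over all probes), and of the 2 other probes of Chek1 1 fell, by 0.65, and 1 did not pass (-0.19, adjusted p = 0.686). The ribosome biogenesis list did not pass (0 of 19, camera adjusted p = 0.447).

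Crypt base genes fell in 6 of 19 cases (7 fell and 2 rose adjusted over the list alone, median -0.23, camera adjusted p = 0.0014). Clca4 fell by 1.18, the receptor gene Tnfrsf19 by 0.69 and the Wnt feedback gene Axin2 by 0.56. The Wnt list (1 of 14 rose and 3 fell, 3 and 4 adjusted over the list alone, camera adjusted p = 0.568), the position +4 list (2 of 7 fell; 0.0825) and the Notch list (1 of 14 rose and 3 fell, 1 and 5 adjusted over the list alone, 0.0999) did not pass. Within the Notch list Jag1 rose by 0.98 and the glycosyltransferase gene Mfng fell by 0.97. Control values of Mfng were 5.57 to 6.08, so its irradiated mean lay near the lowest detected signals there (4.95 to 5.26). The size of that fall is thus uncertain. Fetal-like genes rose in 16 of 21 cases (17 adjusted over the list alone, median 1.21, camera adjusted p = 1.31e-25). Tm4sf4 rose 3.49-fold and Ly6a 2.28-fold. Of 11 YAP targets, 4 rose (4 adjusted over the list alone, median 0.25, camera adjusted p = 0.000823), with Areg at 3.20-fold and F3 at 3.02-fold. Of 14 inflammation genes, 4 rose and 1 fell (median 0.28, camera adjusted p = 0.00166), with Il18 at 2.19-fold, and none of 10 interferon genes passed (camera adjusted p = 0.209).

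Enterocyte genes rose in 22 of 28 cases (23 adjusted over the list alone, median 0.62, camera adjusted p = 3.67e-22). Slc15a1 rose 2.92-fold, Krt20, a keratin of villus cells, 2.34-fold and the apolipoprotein gene Apoc3 2.18-fold. HNF4A targets rose in 13 of 24 cases and fell in 2 (14 and 2 adjusted over the list alone, median 0.47, camera adjusted p = 3.71e-08), with Apoc2 at 3.99-fold. Hnf4a itself did not pass (log2 fold change -0.17, adjusted p = 0.398), and among the 21 transcription factors 1 rose and 2 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.83). Xenobiotic metabolism genes rose in 14 of 21 cases (15 adjusted over the list alone, median 0.51, camera adjusted p = 4.15e-14), with Cyp3a11 at 3.19-fold and Cyp2c29 at 2.38-fold. The fatty acid oxidation list did not pass (3 of 21 rose and 2 fell, 5 and 4 adjusted over the list alone, camera adjusted p = 0.0703), although Acaa1b rose by 0.99. It passed without control 48 h replicate 2 (adjusted p = 0.0456), control 48 h replicate 3 (adjusted p = 0.0331) or irradiated 48 h replicate 3 (adjusted p = 0.0467).

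Enteroendocrine genes rose in 11 of 25 cases (14 adjusted over the list alone, median 0.62, camera adjusted p = 6.29e-11), with Chga at 2.57-fold and the hormone genes Tac1 and Nts at 2.28-fold and 2.27-fold. Paneth cell genes rose in 6 of 15 cases (7 adjusted over the list alone, median 0.26, camera adjusted p = 6.3e-05; adjusted p = 0.0797 with an estimated correlation). Pnliprp2, a lipase gene, rose by 0.79 and Ang4 by 0.69, while the probes of Lyz1 differed, the brighter one not passing (0.13, adjusted p = 0.432) and the other rising by 0.51 (adjusted p = 0.0165 over all probes). The goblet list went both ways, with 5 of 16 higher and 4 lower (6 and 5 adjusted over the list alone). Its median was -0.07, its mean 0.08 and the direction of its test up, and it did not pass (camera adjusted p = 0.362). The goblet genes 1810010M01Rik, Scin and Clca3 rose 2.75-fold, 2.51-fold and 2.29-fold. Of 9 tuft cell genes 2 fell (camera adjusted p = 0.122), among them Kctd12, by 0.60.

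Hypoxia and glycolysis genes fell in 7 of 18 cases (9 adjusted over the list alone, median -0.27, camera adjusted p = 1.52e-05), with Ankrd37 at -1.68, the pyruvate dehydrogenase kinase gene Pdk1 at -1.05 and Egln3 at -0.78. Cholesterol synthesis genes fell in 9 of 19 cases (11 fell and 1 rose adjusted over the list alone, median -0.30, camera adjusted p = 3.12e-05), with Stard4 at -0.70 and the transcription factor gene Srebf2 at -0.51. NRF2 and glutathione genes rose in 10 of 20 cases (13 adjusted over the list alone, median 0.32, camera adjusted p = 1.18e-08), with the cystine transporter gene Slc7a11 at 2.88-fold and the sulfiredoxin gene Srxn1 at 1.80-fold. The stress response list (2 of 20 rose and 4 fell, camera adjusted p = 0.137) and the oxidative phosphorylation list (0 of 25; 0.764) did not pass. Of 3 mesenchyme genes 2 rose, including vimentin (Vim), by 0.87 (camera adjusted p = 0.0703). The immune list did not pass (0.37), although Laptm5, a lysosomal protein gene of leukocytes, fell by 0.92, and neither did the endothelial list (0.878). The erythroid list held 1 measured gene, Epb4.2, which encodes a red cell membrane protein and fell by 0.71 (camera adjusted p = 0.0437; adjusted p = 0.0679 with an estimated correlation); the list call was lost without control 48 h replicate 4 (adjusted p = 0.0767).

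Clone names left out, Mcam, an adhesion molecule gene, had the largest rise at 48 h (2.37), followed by Mbl2 (2.37). The placental prolactin family genes Prl2c3, Prl2c5 and Prl2c4 rose 4.88-fold, 4.59-fold and 4.01-fold. Their sequences are nearly identical, so probes may read more than 1 of them and their separate values are uncertain. The array name Prl2c4 matches the current symbol Prl2c3, so the entries Prl2c3 and Prl2c4 may be the same gene. Anxa8, Sprr1a, the costimulatory gene Cd86 (2.08), Psca (2.05) and Apoc2 completed the 10 largest. Among the largest falls were those in Ankrd37, the uroplakin family gene Upk3b (-1.61, with its 2 other probes at -1.29 and, not called, -0.16), the nuclear receptor gene Nr2e3 (-1.51), Gvin1 (-1.48), Slc16a12 (-1.36), Kank1 (-1.35), the cytochrome gene Cyp2s1 (-1.31), the retinoid carrier gene Rbp7 (-1.30) and Rcor2 (-1.29).

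At 48 h, 788 genes were higher and 675 lower, 194 and 37 of them by at least 2-fold. Values did not overlap in 1315 of them, and in 2209 of all genes tested against 309 given by chance. With median scaling 402 genes were higher and 936 lower (30.0% higher against 53.9%), and with array weights 1342 were lower. The lower count was 439 without control 48 h replicate 3, 426 without irradiated 48 h replicate 3 and 436 without irradiated 48 h replicate 4. Without a detection filter the apoptosis, tuft cell, fatty acid oxidation and stress response lists passed (camera adjusted p = 0.0494, 0.0228, 0.0243 and 0.0494), and with the histone covariate the apoptosis and fatty acid oxidation lists did (0.037 and 0.0124). With median scaling the position +4 and mesenchyme lists passed (0.0374 and 0.0136), the former also without the 5 arrays with fewest detected probes (0.0465). The erythroid call was lost with median scaling (0.066), the processed values of the authors (0.133), no filter (0.879), the covariate of detected probes (0.0514) and without the 5 arrays (0.0511).

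**Figure D3:**
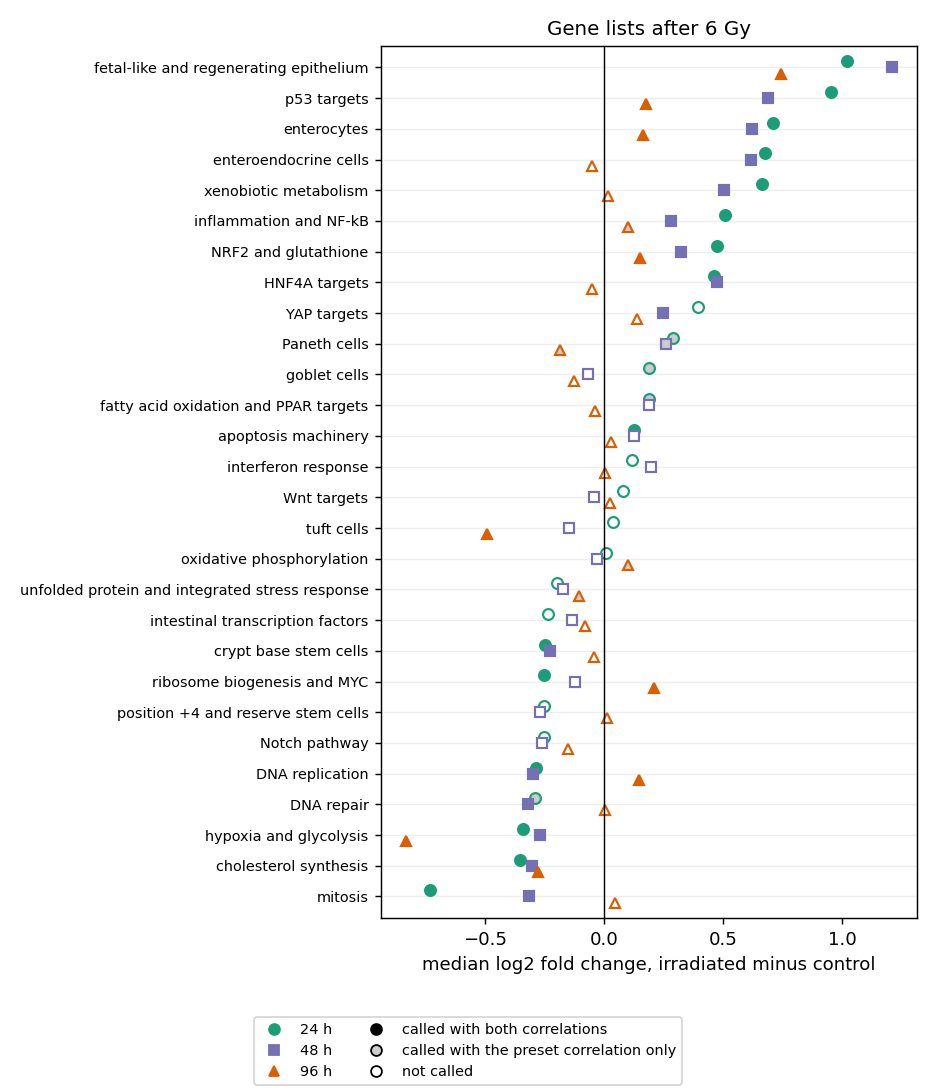
Median log2 fold change (horizontal axis, irradiated minus control) of the tested genes of 28 lists (vertical axis) at 24 h (circles), 48 h (squares) and 96 h (triangles), filled where camera called the list with both the preset and an estimated correlation, grey with the preset one only, and open where the list was not called. Fetal-like genes lay at 1.02, 1.21 and 0.74, and hypoxia and glycolysis genes at -0.34, -0.27 and -0.84; with median scaling, relative to the shift of all genes, oxidative phosphorylation at 96 h was the called list that turned (-0.03 against 0.10).

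At 96 h, genes induced by low oxygen were lower in irradiated organoids and fetal-like genes remained among the higher ones, while most p53 targets and all but 6 enterocyte genes no longer passed as higher. Egln3, the oxygen-sensing prolyl hydroxylase that is itself induced by hypoxia, fell from 10.34 ± 0.22 to 8.19 ± 0.25 log2 units (mean ± SD, n = 4 arrays each; log2 fold change -2.15, SE 0.13, limma adjusted p = 7.51e-11). Vegfa, the angiogenic growth factor gene, fell by 1.53 (SE 0.14, adjusted p = 1.12e-07). Reg3b rose 4.56-fold (log2 fold change 2.19, SE 0.11, adjusted p = 1.04e-11), and mesothelin (Msln) rose 3.76-fold (SE 0.14, adjusted p = 2.23e-09). Cdkn1a did not pass (log2 fold change -0.23, adjusted p = 0.318), with controls at 9.57 to 9.87 log2 units, against 8.42 to 8.84 in the 48 h controls.

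Hypoxia and glycolysis genes fell in 16 of 18 cases and rose in none, the same numbers when adjusted over the list alone (median -0.84, camera adjusted p = 6.23e-29). Ankrd37 fell 3.88-fold. Fetal-like genes rose in 11 of 21 cases (12 adjusted over the list alone, median 0.74, camera adjusted p = 1.56e-18), with the alarmin gene Il33 at 2.62-fold, Anxa3 at 1.26 on the log2 scale and Ly6a at 2.02-fold. Of 28 p53 targets, 5 rose (9 adjusted over the list alone, median 0.17, camera adjusted p = 0.000424), with Zmat3 at 1.90-fold, Trp53inp1 at 1.67-fold and Ccng1 at 1.58-fold (other probes 0.64 and, not called, 0.40 on the log2 scale). The brightest probe of Mdm2 did not pass (0.44, adjusted p = 0.074), and did so without control 96 h replicate 1 (0.60, adjusted p = 0.00377). The 2 other probes of Mdm2 rose by 0.48 and 0.68 (adjusted p = 0.00934 and 0.0454 over all probes). The YAP list did not pass (1 of 11 rose, camera adjusted p = 0.29); its higher member was Areg, by 0.65. Of 14 inflammation genes 2 rose, Reg3b and Il18 (0.85). That list passed at a camera adjusted p of 0.0384 and was lost with an estimated correlation (adjusted p = 0.0514) and without control 96 h replicate 2 (0.0697), control 96 h replicate 3 (0.0505) or irradiated 96 h replicate 4 (0.105).

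Proliferation lists no longer lay below the controls. DNA replication genes were slightly higher as a group (median 0.14, 1 of 29 rose, also 1 adjusted over the list alone, camera adjusted p = 0.00714). The single called gene was Tk1, which rose by 0.38 (adjusted p = 0.0296), and its call was lost without control 96 h replicate 3 (adjusted p = 0.0783) or 4 (0.113), or irradiated 96 h replicate 2 (0.0501), 3 (0.114) or 4 (0.0582). The other probe of Tk1 did not pass (0.49, adjusted p = 0.064 over all probes). Ribosome biogenesis genes likewise lay higher (median 0.21, none of 19 alone, camera adjusted p = 0.00134). Mitosis (median 0.05, camera adjusted p = 0.158), DNA repair (0.726) and apoptosis (0.481) did not pass, with no gene called in any of the 3. Lgr5 still fell, by 0.50 (adjusted p = 0.0224), a call that was lost without control 96 h replicate 2 (-0.36, adjusted p = 0.0664), irradiated 96 h replicate 3 (-0.51, adjusted p = 0.05) or irradiated 96 h replicate 4 (-0.48, adjusted p = 0.067). Olfm4 did not pass (-0.04, adjusted p = 0.875). The crypt base (1 of 19 rose and 2 fell, camera adjusted p = 0.555), position +4 (0 of 7; 0.68), Wnt (2 of 14 rose and 1 fell; 0.646) and Notch lists (1 of 14 rose; 0.615) did not pass.

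Enterocyte genes rose in 6 of 28 cases and fell in 1 (6 and 4 adjusted over the list alone, median 0.16, camera adjusted p = 0.0129), with Mep1b at 2.20-fold and Krt20 at 1.68-fold. HNF4A targets (3 of 24 rose and 3 fell, 3 and 4 adjusted over the list alone, camera adjusted p = 0.612), intestinal transcription factors (0 of 21; 0.646), fatty acid oxidation (1 of 21 rose and 4 fell; 0.239) and xenobiotic metabolism (4 of 21 rose and 1 fell, 4 and 2 adjusted over the list alone, 0.158) did not pass. Among their members the actin-bundling gene Espn fell by 1.53, Apoc2 rose by 0.78, Cyp2c29 rose by 1.19 and Cyp2c55 fell by 0.64. Hnf4a did not pass (-0.23, adjusted p = 0.308).

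Paneth cell genes fell in 4 of 15 cases (6 adjusted over the list alone, median -0.19, camera adjusted p = 0.000424; adjusted p = 0.138 with an estimated correlation), with Nupr1, a stress-induced chromatin protein gene, at -0.85. Lyz1 fell by 0.32 (adjusted p = 0.0472). That call was lost without control 96 h replicate 3 (adjusted p = 0.131) or 4 (0.142), or irradiated 96 h replicate 1 (0.128), 3 (0.109) or 4 (0.0892). Tuft cell genes fell in 3 of 9 cases (4 adjusted over the list alone, median -0.50, camera adjusted p = 0.00464), with Kctd12 at -0.84, and the list was lost without irradiated 96 h replicate 2 (adjusted p = 0.0501). The goblet list did not pass (3 of 16 rose and 1 fell, median -0.13, mean 0.09, camera adjusted p = 0.646), but 1810010M01Rik, Scin and Clca3 rose by 1.29, 0.99 and 0.93. Enteroendocrine genes did not pass (2 of 25 rose and 1 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.68), nor did Chga (0.56, adjusted p = 0.389; 0.17 without control 96 h replicate 1).

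Cholesterol synthesis genes fell in 4 of 19 cases (8 adjusted over the list alone, median -0.28, camera adjusted p = 1.93e-06), with the sterol sensor gene Insig1 at -0.45 and Lss at -0.41. In the stress response list 5 of 20 fell (6 adjusted over the list alone, median -0.11, camera adjusted p = 0.00781; adjusted p = 0.156 with an estimated correlation), among them Chac1 (-2.14), the pseudokinase gene Trib3 (-1.71) and Atf3 (-0.96). The list was lost without control 96 h replicate 1 (adjusted p = 0.0503) or 2 (0.118). NRF2 genes rose in 2 of 20 cases (6 adjusted over the list alone, median 0.15, camera adjusted p = 0.00054), including the glutathione transferase gene Gsta1, by 0.45. Oxidative phosphorylation passed with a median of 0.10 and no single gene called (camera adjusted p = 0.0438). It was lost with an estimated correlation (adjusted p = 0.0514) and without control 96 h replicate 1 (0.0784), 3 (0.0579) or 4 (0.0826) or irradiated 96 h replicate 2 (0.0936) or 3 (0.0691). The interferon (camera adjusted p = 0.809), mesenchyme (0.713), immune (0.582) and endothelial (0.727) lists did not pass, with Laptm5 at -0.91. In the erythroid list Epb4.2 fell by 0.74 (camera adjusted p = 0.0129).

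Clone names left out, the largest rises at 96 h included, besides Reg3b and Msln, the serpin gene Serpinb9b (1.88) and the cornified envelope gene Lor (1.81). Prl2c5 and Prl2c4, not above background in controls, were at least 2.80-fold and 2.23-fold higher, and Prl2c3 rose by 1.53. The major urinary protein genes Mup1, Mup5 and Mup2 rose by 1.96, 1.82 and 1.46. Both families have nearly identical members, so their separate values are uncertain. The clone name 4930583H14Rik, now Mgarp, was left out and fell further than the genes named (-3.48, -3.45 and -4.38 at 24, 48 and 96 h). Among the other largest falls were those in Upk3b (-2.91), Egln3, Chac1, the chymotrypsinogen gene Ctrb1 (-2.11), the manganese transporter gene Slc30a10 (-1.99) and Ak3l1 (-1.96). Ankrd37, the lactate transporter gene Slc16a3 (-1.95), the collagen prolyl hydroxylase gene P4ha2 (-1.86) and Mpp4 were also among them, Mpp4 not above background after irradiation and at least 2.03-fold lower. The other probes of Slc16a3 (-0.23), Mup5 (0.12) and Trib3 (-0.25) did not pass (adjusted p = 0.571, 0.752 and 0.621 over all probes). Of the 2 other probes of Espn 1 fell, by 1.33, and 1 did not pass (0.25, adjusted p = 0.700).

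At 96 h, 186 genes were higher and 366 lower, 43 and 69 of them by at least 2-fold. Values did not overlap in 457 of them, and in 815 of all genes tested against 309 given by chance. With median scaling the split was 71 and 559 (11.3% higher against 33.7%), with array weights 105 and 210, and with the mean of histone genes as a covariate 401 and 573. The counts were 93 and 152 without the 5 arrays that had the fewest detected probes, and 52 and 113 when the 8 arrays of this time were fitted alone. Of the 8 lists called higher, median scaling ended the calls of DNA replication (camera adjusted p = 0.505), enterocytes (0.67), ribosome biogenesis (0.137), NRF2 (0.505) and oxidative phosphorylation (0.92, with a negative median), and of the lower ones those of tuft cells (0.137) and the erythroid gene (0.137). Without those 5 arrays the calls of enterocytes (0.153), inflammation (0.0582) and oxidative phosphorylation (0.153) were lost. The inflammation call was also lost without a detection filter (0.162) and with the covariate of detected probes (0.0627) or histones (0.0688), oxidative phosphorylation with the former covariate (0.0627), and the erythroid call with the processed values of the authors (0.0607) or no filter (0.573).

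**Figure D4:**
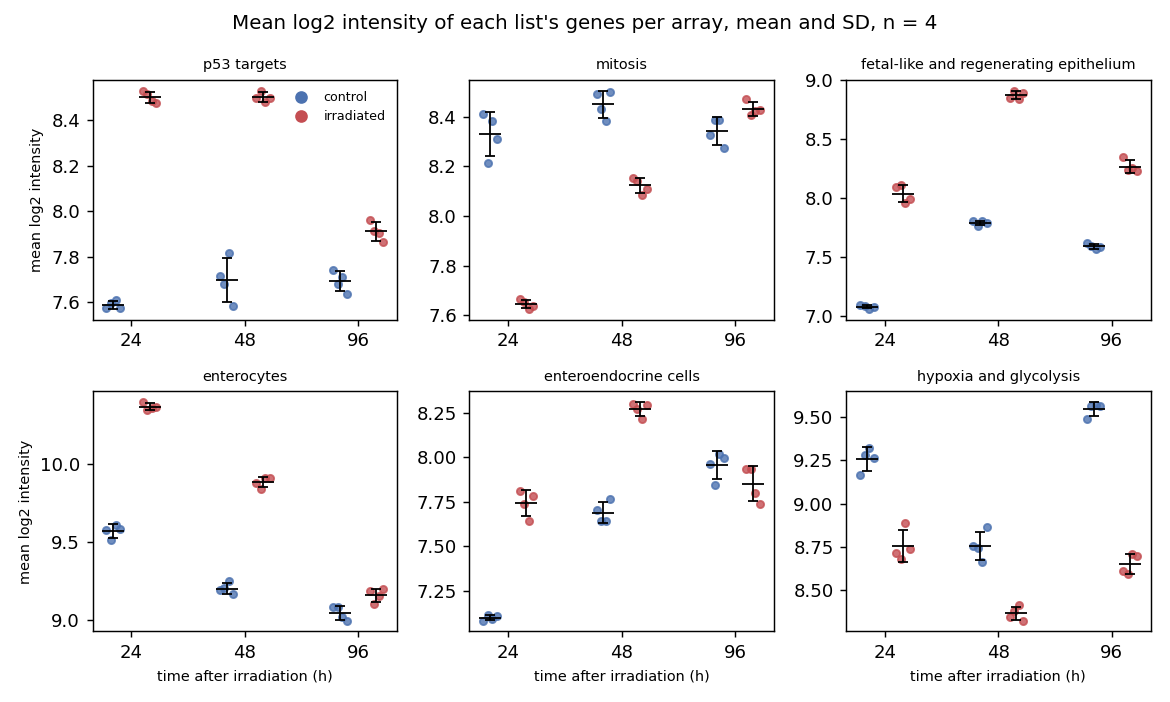
Mean log2 intensity (vertical axis) over the tested genes of 6 lists, 1 point per array, at 24, 48 and 96 h (horizontal axis) in control (blue) and irradiated (red) organoids, with bars at the mean and SD of 4 arrays. Mitosis genes lay lower in all irradiated arrays at 24 and 48 h, and hypoxia and glycolysis genes lay lower in all irradiated arrays at each time, most at 96 h (median -0.84).

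Effects were partly shared between times. Of the genes higher at 24 h, 574 were also higher at 48 h (87.9 if the lists were independent), and 403 were lower at both (84.6). Between 48 and 96 h the shared numbers were 129 higher (13.6) and 136 lower (22.9), and between 24 and 96 h 121 (20.7) and 120 (45.9). At all 3 times 109 genes were higher and 78 lower. Across genes, which are not independent replicates, effects correlated at r = 0.69 between 24 and 48 h, 0.42 between 48 and 96 h and 0.31 between 24 and 96 h.

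Testing the difference between effects directly, the fall of mitosis genes was smaller at 48 h than at 24 h, and the rises of p53 target, enterocyte and enteroendocrine genes were smaller at 96 h than at either earlier time. Controls moved too. From 24 to 96 h enteroendocrine genes rose in controls (median 0.82), enterocyte genes fell (-0.55) and p53 targets did not pass (0.08, camera adjusted p = 0.183). A smaller effect therefore need not mean a lower level in irradiated organoids. From 24 to 48 h the mitosis list shifted by a median of 0.32 (1 of 21 genes adjusted over the list alone, 0 over all genes, camera adjusted p = 5.74e-06). The goblet, ribosome biogenesis and erythroid lists also passed there (-0.22, 0.15 and -0.81) but were lost with an estimated correlation (adjusted p = 0.136, 0.136 and 0.112). Olfm4 moved by 0.63 (limma adjusted p = 0.0303), Ly6a by -0.92 (adjusted p = 0.00774) and Ascl2 by -1.51 (adjusted p = 0.000282). Irradiated values of Ly6a lay at 8.41 to 8.70 at 24 h and at 9.95 to 10.21 at 48 h. Its control values lay at 6.15 to 6.66 and at 8.75 to 9.02. Ly6a thus rose in both, and more in controls, with time and chip not told apart. The largest positive differences were in involucrin (Ivl; 1.97, SE 0.20, adjusted p = 2.0e-05; from -0.11 to 1.86), Anxa8 (1.43), Nrn1 (1.34), Dse (1.26) and Nupr1 (1.18). The largest negative ones were in Pabpc2 (-2.17; from 2.23 to 0.06), Snn (-1.93), Cxcr5 (-1.89), Stk10 (-1.87) and Fmnl3 (-1.83). In all 27 differences were positive and 81 negative, and with median scaling 14 and 19. The positive count was 16 without control 24 h replicate 3, irradiated 24 h replicate 3 or irradiated 48 h replicate 2, 17 without control 48 h replicate 1 or 3, and 45 without irradiated 24 h replicate 1; the negative count was 52 without control 24 h replicate 3.

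From 48 to 96 h the irradiation effect on enterocyte genes shifted by a median of -0.55 (12 of 28 fell, 17 adjusted over the list alone, camera adjusted p = 4.41e-15), on enteroendocrine genes by -0.79 (9 of 25, 13 adjusted over the list alone; 1.34e-12) and on p53 targets by -0.59 (7 of 28, 15 adjusted over the list alone; 1.14e-12). Hypoxia genes shifted by -0.58 (8 of 18, 9 adjusted over the list alone, camera adjusted p = 7.16e-10), and xenobiotic metabolism, HNF4A target, Paneth cell and fetal-like genes shifted by -0.53, -0.50, -0.45 and -0.31, where 5 of 21, 10 of 24, 3 of 15 and 3 of 21 fell (11, 11, 8 and 8 adjusted over the list alone). DNA replication (0.37, 4 of 29, camera adjusted p = 5.74e-10), mitosis (0.39, 1 of 21), DNA repair (0.29, 0 of 23), ribosome biogenesis (0.22, 1 of 19) and crypt base genes (0.14, 3 of 19) shifted up. Adjusted over the list alone these counts were 12, 9, 7, 3 and 4. Position +4, YAP, fatty acid oxidation and NRF2 genes passed with the preset correlation and were lost with an estimated correlation (adjusted p = 0.0627, 0.0692, 0.0729 and 0.0887). Cdkn1a moved by -1.52 (limma adjusted p = 1.38e-05), Olfm4 by 0.61 (adjusted p = 0.0173) and Egln3 by -1.37. Control values of Cdkn1a lay at 8.42 to 8.84 log2 units at 48 h and at 9.57 to 9.87 at 96 h. Irradiated values lay at 9.70 to 10.12 and at 9.35 to 9.66. Controls of Cdkn1a thus rose more than its irradiated values fell, with time and chip not told apart. Control values of Egln3 lay at 8.8 to 9.0 at 48 h and at 10.1 to 10.6 at 96 h. Its irradiated values lay at 8.0 to 8.3 and at 7.9 to 8.5, so its shift lay in the controls. The hypoxia and glycolysis list also rose in controls over this interval, by a median of 0.73. The largest positive differences were in Dmbt1, an epithelial scavenger receptor gene (1.28, adjusted p = 1.08e-05; from -1.23 to 0.05), Clca4 (1.04), Pla2g4b (1.04), Zfp101 (1.00) and Slc16a12 (0.97). The call for Zfp101 was lost without control 48 h replicate 2 (adjusted p = 0.0545) or 3 (0.0538), irradiated 48 h replicate 4 (0.0575) or control 96 h replicate 3 (0.0528). Among the largest negative ones were those in the phosphatase gene Dusp1 (-2.52, adjusted p = 3.0e-08; from 0.70 to -1.82), Slc30a10 (-2.21), Oasl1 (-1.91) and Mbl2 (-1.77). In all 88 differences were positive and 293 negative, and with median scaling 3 and 121. The positive count was 41 without control 48 h replicate 1 or irradiated 48 h replicate 3, 50 and 56 without control 48 h replicates 2 and 3, 51 without irradiated 48 h replicate 4 or irradiated 96 h replicate 3, and 58 without control 96 h replicate 3.

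From 24 to 96 h the effect on mitosis genes shifted by a median of 0.75 (15 of 21 rose, 20 adjusted over the list alone, camera adjusted p = 5.44e-13) and that on p53 targets by -0.66 (16 of 28 fell, 19 adjusted over the list alone; 6.06e-12). Ribosome biogenesis (0.52, 6 of 19), DNA replication (0.42, 8 of 29) and crypt base genes (0.25, 5 of 19) shifted up, with 11, 12 and 7 genes adjusted over the list alone. Enterocyte (-0.60, 17 of 28, camera adjusted p = 5.64e-14), enteroendocrine (-0.60, 9 of 25), xenobiotic metabolism (-0.54, 12 of 21), Paneth cell (-0.53, 7 of 15), HNF4A target (-0.50, 11 of 24), fetal-like (-0.40, 6 of 21), fatty acid oxidation (-0.27, 3 of 21) and hypoxia genes (-0.26, 7 of 18) shifted down. Adjusted over the list alone these counts were 22, 14, 17, 8, 12, 9, 5 and 7. Calls for DNA repair, goblet, tuft, NRF2 and erythroid genes were lost with an estimated correlation (adjusted p = 0.076, 0.101, 0.11, 0.104 and 0.0872). Lgr5 moved by 0.97 (limma adjusted p = 0.00116), Olfm4 by 1.24 (adjusted p = 9.79e-06), Lyz1 by -0.69 (adjusted p = 0.00138) and Tk1 by 1.36. The largest positive differences were in Cdc25c, a phosphatase gene of mitotic entry (1.85), Clca4 (1.69), Dmbt1 (1.46), Nrn1 (1.44) and Ccdc18 (1.44). The largest negative ones were in Cxcr5 (-2.94), Cacna1f (-2.89), Stk10 (-2.88), Fmod (-2.78) and V1rh21 (-2.77). In all 487 differences were positive and 751 negative. With median scaling these counts were 301 and 172, with cyclic loess 283 and 941, and without the 5 arrays that had the fewest detected probes 171 and 413.

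Of the lists called with the preset correlation, 15 of 19 at 24 h, 15 of 17 at 48 h and 10 of 14 at 96 h were also called with an estimated correlation; each of the others is named with that p. Where a list at a single time has no separate count adjusted over the list alone, that count was the same as over all genes. Median scaling shifted the median of all genes by -0.44, -0.21 and -0.21 at the 3 times. Relative to that shift, every gene the naming rule picked and limma called at a time kept its direction (97, 93 and 69 genes). The genes were picked as called before this scaling, and subtracting the shift centers all genes again, so this outcome was close to set in advance. Without the subtraction, 251 of 296 values of picked genes, over all contrasts, kept direction and side of the threshold. Of the others 44 lost the call and 1 reversed.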

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

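The tests of the 10 largest rises at 24 h and of the hypoxia and glycolysis list at 96 h were chosen after the result was seen. The 10 largest rises at 24 h had a median log2 change of 2.80, and 2.74 without the 5 arrays with fewest detected probes, so they did not rest on those arrays. The naming rule required that irradiated and control values did not overlap, so this outcome was partly set by how the genes were picked. Within groups the 10 genes varied together, with a median pair correlation of 0.40 (-0.21 to 0.97) against at most 0.30 in 1000 matched random sets (median 0.01, 95th percentile 0.15, 99th 0.24), so probes reading a shared sequence may contribute, though common regulation would give the same value. Of the other probes, 1 of Duxbl, detected on all 24 arrays, rose by 2.76, as its first probe did (2.63), while 3 probes of Abca8b and Fmnl3, detected on 4 or 5 arrays, changed by 0.68, 0.30 and 0.63. The median of these 4 was 0.66, a limit on detection set after all 10 other probes of 7 genes had given 0.21, and it leaves open for the other genes whether the signals reflect the genes named. Of 29 immune and mesenchymal markers with a probe, 23 were detected on no irradiated 24 h array. On all 4 irradiated 24 h arrays 1 was detected, against 3 on all 4 controls. Of the 8 that passed the detection filter, 2 rose and 1 fell. The irradiated 24 h arrays also detected fewer probes in general (a mean of 11469 against 13012 in controls), so markers missing there weigh less. Whether immune or mesenchymal cells were added stays open for these markers.

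The hypoxia and glycolysis list at 96 h had a median of -0.84, and -0.83 without the 5 arrays with fewest detected probes, which argues against those arrays as the source. In controls the list rose between 48 and 96 h, with 14 of 18 genes called, 16 adjusted over the list alone (median 0.73, camera adjusted p = 1.1e-25, 1.59e-07 with an estimated correlation), led by Ankrd37 (1.57), Egln3 (1.41) and Ero1l (1.25). Between 24 and 48 h 11 had fallen in controls, 12 over the list alone (median -0.48, adjusted p = 4.36e-09, 0.000139 with an estimated correlation). These changes in controls lie between chips, whereas the fall at 96 h compares arrays of 1 chip. An effect of irradiation, the biological explanation, stays open, and position on the chip cannot be told apart from it.

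Single samples stood apart from the other 3 of their group in 22 of 428 groups of log2 values, median signals or numbers of detected probes, where chance at about 1 in 20 gives 21.4. In control 24 h replicate 2 these were Ascl2 (6.11, others 5.82 to 5.85) and Ddit4l (5.11, others 4.54 to 4.63), and in replicate 3 Stc2 (9.90, others 9.70 to 9.72). Irradiated 24 h replicate 3 was low for Acaa1b (10.47, others 10.54 to 10.55), Anxa1 (7.27, others 7.49 to 7.52) and Fas (6.19, others 6.66 to 6.73), replicate 1 low for Ankrd37 (6.91, others 7.33 to 7.36), and replicate 2 high for Chga (10.16, others 9.57 to 9.60). Control 48 h replicate 4 stood apart for Areg (9.05, others 9.41 to 9.49), Bax (9.67, others 9.46 to 9.48), Clca3 (9.44, others 9.92 to 9.99), Kctd12 (6.90, others 7.07 to 7.08) and Lyz1 (12.37, others 12.09 to 12.13), and replicate 3 for Jag1 (7.68, others 7.85 to 7.88) and Mfng (5.57, others 6.00 to 6.08). Irradiated 48 h replicate 4 was high for Axin2 (9.42, others 9.29 to 9.31), replicate 2 for Hnf4a (10.03, others 9.69 to 9.70) and replicate 3 for Krt20 (10.82, others 10.64 to 10.66). Control 96 h replicate 1 was low for Chga (8.87, others 10.31 to 10.60) and Upk3b (7.90, others 8.58 to 8.63), replicate 2 high for Lgr5 (9.03, others 8.42 to 8.52), and irradiated 96 h replicate 2 high for Atf3 (5.21, others 4.66 to 4.74).

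Effects of irradiation differed between times for gene lists by camera on the difference itself, with both the preset and an estimated correlation. From 24 to 48 h the median difference was 0.32 for mitosis. From 48 to 96 h it was -0.59 for p53 targets, 0.39 for mitosis, 0.37 for DNA replication, 0.29 for DNA repair, 0.14 for crypt base stem cells, -0.31 for fetal-like epithelium, -0.55 for enterocytes, -0.50 for HNF4A targets, -0.45 for Paneth cells, -0.79 for enteroendocrine cells, 0.22 for ribosome biogenesis, -0.58 for hypoxia and glycolysis and -0.53 for xenobiotic metabolism. From 24 to 96 h it was -0.66 for p53 targets, 0.75 for mitosis, 0.42 for DNA replication, 0.25 for crypt base stem cells, -0.40 for fetal-like epithelium, -0.60 for enterocytes, -0.50 for HNF4A targets, -0.53 for Paneth cells, -0.60 for enteroendocrine cells, -0.27 for fatty acid oxidation, 0.52 for ribosome biogenesis, -0.26 for hypoxia and glycolysis and -0.54 for xenobiotic metabolism.

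Effects on single genes differed between times by limma. From 24 to 48 h they differed for Olfm4 (0.63), Ly6a (-0.92), Ascl2 (-1.51), Ivl (1.97), Anxa8 (1.43), Nrn1 (1.34), Dse (1.26), Nupr1 (1.18), Pabpc2 (-2.17), Snn (-1.93), Cxcr5 (-1.89), Stk10 (-1.87) and Fmnl3 (-1.83). From 48 to 96 h they differed for Cdkn1a (-1.52), Olfm4 (0.61), Egln3 (-1.37), Dmbt1 (1.28), Clca4 (1.04), Pla2g4b (1.04), Zfp101 (1.00), Slc16a12 (0.97), Dusp1 (-2.52), Slc30a10 (-2.21), Oasl1 (-1.91) and Mbl2 (-1.77). From 24 to 96 h they differed for Lgr5 (0.97), Olfm4 (1.24), Lyz1 (-0.69), Tk1 (1.36), Cdc25c (1.85), Clca4 (1.69), Dmbt1 (1.46), Nrn1 (1.44), Ccdc18 (1.44), Cxcr5 (-2.94), Cacna1f (-2.89), Stk10 (-2.88), Fmod (-2.78) and V1rh21 (-2.77).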

How the results depend on the processing

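The settings with a covariate, those without the 5 arrays with fewest detected probes and the leave-one-out tests of gene lists were chosen after seeing the data. Of 5308 values of genes picked by the naming rule under the other settings, 4926 kept direction and side of the threshold, 374 lost the call, 7 gained it and 1 reversed. Under leave-one-out 2459 of 2608 did, 148 lost the call and 1 gained it. Most of these genes were picked because they were called in these same data, so both shares were partly set in advance. Ccnd1 at 96 h reversed from 0.30 to -0.01 with median scaling, and the oxidative phosphorylation list at 96 h from 0.10 to -0.24. That scaling moved the median of all genes at 96 h by -0.21, and relative to it the values were 0.20 and -0.03, so the shift accounts for the turn of Ccnd1. Signals near background limit these arrays, since a probe below detection gives only a bound.

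With median scaling, genes higher and lower were 464 and 4925 at 24 h, 402 higher at 48 h, 71 and 559 at 96 h, 14 and 19 for 48 minus 24 h, 301 and 172 for 96 minus 24 h, and 3 and 121 for 96 minus 48 h; 3 lists were higher at 96 h (p53 targets, fetal-like and inflammation). With cyclic loess 680 were lower at 24 h and 283 higher for 96 minus 24 h. No background correction gave 133 higher for 96 minus 48 h. For 48 minus 24 h, quantile normalization within each chip gave 45 higher, a stricter detection filter 17 and the mean of all probes 41. Array weights gave 1342 lower at 48 h, 105 and 210 at 96 h, and 131 and 188 for 48 minus 24 h. Fits to the arrays of the times compared gave 52 and 113 at 96 h, 50 higher for 48 minus 24 h and 36 higher for 96 minus 48 h. Fry called 13 lists lower at 48 h; it does not compare a list with other genes. The cause of these changes was not tested.

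An adjusted p under 0.01 gave 792 and 662 at 24 h, 516 and 297 at 48 h, 92 and 193 at 96 h, 8 and 33 for 48 minus 24 h, 166 and 409 for 96 minus 24 h, and 12 and 129 for 96 minus 48 h. A log2 fold change of at least 1 gave 293 and 94, 194 and 37, 43 and 69, 12 and 47, 69 and 302, and 3 and 124 in the same order. Both are stricter by construction.

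Leaving out the 5 arrays with fewest detected probes, which also left fewer samples, gave 680 lower at 24 h and 93 and 152 at 96 h. For differences between times it gave 13 higher for 48 minus 24 h, 171 and 413 for 96 minus 24 h, and 23 and 146 for 96 minus 48 h. At 96 h 5 lists were then higher (p53 targets, DNA replication, fetal-like, ribosome biogenesis and NRF2). The number of detected probes as covariate gave 789 lower at 24 h. The histone mean as covariate gave 401 and 573 at 96 h, 71 and 125 for 48 minus 24 h, 1180 higher for 96 minus 24 h, and 223 and 483 for 96 minus 48 h.

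With the replicate block, 16 genes were higher for 48 minus 24 h and 42 for 96 minus 48 h, and the other counts moved by at most 1.5 times. The erythroid list at 48 h (camera adjusted p = 0.0748) and the inflammation and oxidative phosphorylation lists at 96 h (0.0913 and 0.0505) were then not called, fatty acid oxidation (0.0491) and mesenchyme (0.0253) at 48 h were, and no other list call changed at a single time. Samples with the same number correlated above 0.1 in 7 of 12 pairs, and 3 of the 12 controls correlated best with their own number, so the numbers were not taken to pair the samples.

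Leaving out 1 array gave 971 to 1196 higher and 922 to 1334 lower at 24 h, 607 to 811 and 426 to 788 at 48 h, and 127 to 253 and 248 to 504 at 96 h. For 48 minus 24 h it gave 16 to 45 and 52 to 89, for 96 minus 24 h 354 to 622 and 599 to 842, and for 96 minus 48 h 41 to 132 and 214 to 347. Lists higher and lower were 12 to 13 and 7 to 7 at 24 h, 10 to 12 and 6 to 7 at 48 h, and 6 to 8 and 5 to 6 at 96 h.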

Other observations

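The leave-one-out and scaling settings of the comparison among controls, and the test of histone genes against the number of detected probes, were chosen after the result was seen. The comparison among controls was added too. Between 24 and 96 h the control organoids gained markers of secretory cells (limma, 733 genes higher and 616 lower of 10798; 332 and 376 with median scaling). Of 25 enteroendocrine markers 18 rose, 21 adjusted over the list alone (median 0.82, camera adjusted p = 3.15e-18, and 8.3e-07 with an estimated correlation). They included Fev, a transcription factor of these cells (1.53), the peptide hormone gene Pyy (1.45) and Neurog3 (1.41), the factor that starts this lineage. Of 15 Paneth cell markers 11 rose, 14 adjusted over the list alone (median 0.75, adjusted p = 3.6e-16, 0.00163 with an estimated correlation), with Habp2 at 2.09 and the matrix protease gene Mmp7 at 2.07. Of 16 goblet cell markers 11 rose and 2 fell, as many over the list alone (median 0.62, adjusted p = 4.8e-07, 0.00114 with an estimated correlation), and Atoh1, the factor of secretory fate, rose by 1.52.

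Absorptive markers went the other way in the controls over the same interval. Of 28 enterocyte markers 16 fell, 19 adjusted over the list alone (median -0.55, adjusted p = 1.22e-14, 7.21e-06 with an estimated correlation), among them the transporter genes Slc6a19 (-1.60) and Slc2a2 (-1.10). Of 21 genes of xenobiotic metabolism 16 fell, 17 over the list alone (median -0.73, adjusted p = 8.82e-19, 8.16e-05 with an estimated correlation), led by Cyp2c29 (-1.86) and Cyp3a11 (-1.70). Of 21 genes of fetal-like epithelium 12 had already risen by 48 h, 14 over the list alone (median 0.59, adjusted p = 3.23e-08, 0.000132 with an estimated correlation), with Anxa1 at 2.48 and the stem cell antigen gene Ly6a at 2.44. From 48 to 96 h 4 of the 21 fell and 1 rose, 4 and 2 over the list alone (median -0.24, adjusted p = 0.0182, 0.0372 with an estimated correlation), a call lost without control 48 h replicate 4 (adjusted p = 0.0814). From 24 to 96 h 9 rose, also 9 over the list alone (median 0.36, adjusted p = 6.13e-08, 6.68e-05 with an estimated correlation). Of 14 Wnt targets 6 rose from 24 to 96 h, 7 over the list alone (median 0.48, adjusted p = 8.49e-06, 0.000553 with an estimated correlation), and of 19 crypt base genes 6 rose and 1 fell, 7 and 1 over the list alone (median 0.32, adjusted p = 0.00717, 0.0113 with an estimated correlation). Epb4.2, the single measured erythroid gene, rose by 1.01 (list adjusted p = 0.0075, 0.02 with an estimated correlation). No mitosis gene was called between 24 and 96 h with limma (median 0.06, camera adjusted p = 0.997, 0 genes over the list alone), and the list was not called under the other settings either, with a median of -0.05 with median scaling. Apart from the fetal-like fall from 48 to 96 h, the list calls given here held with median scaling, cyclic loess and the processed values of the authors, and without any 1 control array of the times compared. Each time lay on its own chip, so time and chip cannot be told apart.

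Histone genes differed between replicates of a group. Over 49 of them the median within-group SD was 0.59, against 0.24 over all genes, and 25 were among the 100 genes with the largest SD, where 0.454 would be expected. Deviations of their mean from the group means correlated at r = -0.61 with those of the DNA replication list over the 24 arrays (permutation p = 6e-05, adjusted 0.00012 over the 2 relations tested, rho = -0.71 with p = 0.00034, r = -0.67 without the 2 farthest arrays), which argues against a larger share of cells in S phase on arrays with more histone signal. With the number of detected probes r was -0.24 (permutation p = 0.167, also after adjustment, rho = -0.34 with p = 0.0875, r = -0.25 without the 2 farthest), so array quality stays open. No other biological explanation was tested.

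Other splits of the arrays into groups of the same size were counted. At 24 h 1 of 35 splits, the true one, called as many genes as the 2558 observed (highest other 34). At 48 h it was again 1 of 35 (1463, highest other 0), and at 96 h 1 of 35 (552). A share of 1 of 35 is the smallest these splits can give, and it was not adjusted over the 3 times. Splits that mix the groups carry the irradiation effect in their spread and so tend to call few genes. Chance is therefore not excluded by these counts. At 96 h another split called 478 genes, that of control replicates 1, 3 and 4 with irradiated replicate 2. It exchanges only control replicate 2 and irradiated replicate 2, so part of the irradiation effect stays in it. Whether its genes differ from the 552 was not tested. The split of control replicates 1 and 3 with irradiated replicates 1 and 2, which balances both groups, called 179. The 96 h samples may therefore also differ in ways other than irradiation. For differences between times 100 splits were drawn. As many genes were called in 2 for 48 minus 24 h (108, highest other 366), in 5 for 96 minus 48 h (381, highest other 830) and in 3 for 96 minus 24 h (1238, highest other 2066). These shares were not adjusted over the 3 differences, and draws that mix the groups tend to call few genes here too. Chance is thus not excluded for any of them, least of all for 96 minus 48 h. Splits that kept or mirrored the true groups at 1 time made up 1 of the 1, 2 of the 4 and 2 of the 2 other draws as large. Without them the highest counts were 0, 501 and 194.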
